A study of Oryza sativa Japonica Group with 30 samples.

How the data were processed

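RNA from developing rice seeds (Oryza sativa, cultivar Nipponbare) was measured on a custom Agilent 44k array with one dye, Cy3, after linear amplification and labelling. The series holds 30 arrays in 10 groups of 3: endosperm, the nutritive tissue of the seed, at 2, 3, 4, 5, 6, 7 and 10 days after pollination (DAP), and embryo at 5, 7 and 10 DAP. The labels number the 3 arrays of each group as replicates but do not state that they came from separate plants, so every p-value measures the spread between samples and nothing wider. Per the labels, endosperm at 2 and 3 DAP was collected as liquid and extracted with one kit, endosperm from 4 to 7 DAP was dissected and extracted with another chemistry, and 10 DAP endosperm came from frozen, ground tissue. The comparisons of 4 with 3 DAP, 10 with 7 DAP and 10 with 2 DAP therefore changed stage and extraction together, and the change of the tissue difference from 5 to 10 DAP spans the endosperm change too. How embryo RNA was extracted is not given in the sources used here, so the tissues may differ in extraction as well.

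The deposited values are log2 signals that the authors had normalized between arrays. The submitters' processing notes name limma 3.38.3, and its role and the background correction are not given in the sources used here. The 2 deposited tables hold 43803 probes each and were identical in all 1314090 values. Sorted values nearly coincided between arrays: array medians ran from 0.26 to 0.33 on the log2 scale, array maxima from 12.84 to 13.05 and minima from -0.37 to -0.20. The zero point of the scale is not stated. Dim probes lie near 0, so a difference from a value near 0 is a difference from background, and the fold of such a probe is understated. The files carry no detection calls, and a level of 1 was used to describe signal over background. At least 1 group mean over 1 was seen for 25.9% of MITE probes and 77.5% of gene and cDNA probes. The correlation between 2 arrays of a group ran from 0.974 to 0.999 across probes, which are not independent replicates. The number of arrays limits the precision of every value.

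Probes were sorted into classes by the codes in their identifiers, read with general knowledge of the rice repeat nomenclature and not from an annotation file. MITEs (miniature inverted-repeat transposable elements, short DNA transposons without genes of their own) had 19041 probes for 10126 element identifiers, 9494 in the forward and 9547 in the reverse orientation of the element. Other classes were other DNA transposons (5294 probes), Ty1-copia (321) and Ty3-gypsy (751) retrotransposons, LINE (38), SINE (107), unclassified retrotransposons (892), Retroryza LTR retrotransposons (472), centromere repeats (2413), rRNA gene repeats (273), telomere repeats (32), unclassified repeats (1486) and miRNA precursors (864). Genes and cDNAs had 11819 probes. The miRNA precursor probes divide into 410 forward and 454 reverse probes, so a value named for a precursor may come from the opposite strand. Which sequence a repeat probe matches elsewhere in the genome was not known, so probes of one family may report a shared transcript. MITE families are named by the code inside the identifier, such as TEMT009, since the files do not pair codes with family names. The files do not pair most gene identifiers with names either.

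One linear model with 10 group means was fitted to all probes with limma 3.58.1 in R 4.3.3, with 20 residual degrees of freedom and moderated variances. The comparisons were an F-test over the 7 endosperm stages, the 6 steps between neighbouring endosperm stages, endosperm at 10 against 2 DAP, embryo against endosperm at 5, 7 and 10 DAP, embryo at 10 against 5 DAP, and the change of the tissue difference from 5 to 10 DAP (an interaction). A probe was called at a Benjamini-Hochberg adjusted p under 0.05 over all 43803 probes with a log2 difference of at least 1 in size, and for the F-test with a range of stage means of at least 1. Differences are log2 differences with their standard error, from 3 arrays per group. Levels are group means with the SD of 3 arrays. In the text, rose, fell, higher and lower refer to probes called this way. MITE counts adjusted over the list alone, that is over the 19041 MITE probes, stand beside the counts over all probes.

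Repeat classes and families of at least 50 probes were tested with camera from limma, which asks whether a set's probes moved differently from all other probes. The correlation within a set was preset at 0.01, and 44 sets were tested in each of 12 comparisons, 528 tests in all, adjusted within each comparison. Of 87 calls, 30 were for the 13 repeat and miRNA classes. With a correlation estimated from the data 1 call held, that of centromere repeats at 4 against 3 DAP. Every other camera call named in the text was lost that way.

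The named probes followed a rule: the largest called rises and falls of genes, of transposable elements and of MITEs in each comparison among probes whose 3 arrays did not overlap the other 3, the largest F among MITEs and genes, and the members of 13 gene lists. The comparisons, thresholds, lists and rule were fixed before the data were examined, except that miRNA precursors were added by the same rule after their values had been seen. The lists hold 140 genes, of which 13 were matched by their rice locus identifier: 2 of 17 seed storage protein genes, 2 of 18 for starch synthesis, 1 of 7 for protein folding in the endoplasmic reticulum (ER), 1 of 13 for DNA replication and the cell cycle, 2 of 13 for small RNA pathways, 1 of 6 for Polycomb PRC2, 1 of 14 embryo markers and 3 of 9 for photosynthesis in green maternal tissue. The lists for endosperm transcription factors, type I MADS-box genes, sugar transport, DNA methylation and reference genes matched 0 probes. Each list had fewer than the 5 probes required for a set test, so only its members were tested. Gene names come from these lists. Counts adjusted over the list alone equalled those over all probes except for the embryo marker RAB16B, which over the list alone passed as lower at 3 against 2 DAP and as higher at 5 against 4 DAP.

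The pipeline was tested on simulated data with noise drawn independently for each probe and array. Deviations that real arrays share were left out, so false calls may be more frequent in the real data. At 10 against 7 DAP it recovered 96 of 100 probes changed by 1.5 and 100 of 100 changed by 3 on the log2 scale, with 0 false calls. For embryo against endosperm at 10 DAP it recovered 98 and 99 of 100, with 1 false call. In 3 comparisons (3 with 2, 6 with 5 and 7 with 6 DAP) deviations from the group mean correlated over 0.1 for all 3 replicate numbers. A shared deviation of replicate 1 alone can give this, so it does not show that the numbers pair the arrays. A replicate block added to the model called 1370, 339 and 975 probes there. Alternatives covered renormalization, array weights, filters, the fold minimum, the variance model, the set test and leaving out arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.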

Results

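The data were 30 arrays of 43803 probes: endosperm at 7 stages from 2 to 10 DAP and embryo at 3 stages, with 3 arrays per group. The series asks which MITE transcripts appear as the endosperm develops, and the embryo serves as the second seed tissue. Array depth has no count; the lowest and highest array medians were 0.26 and 0.33 on the log2 scale.

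Across the 7 endosperm stages, the measured storage and starch genes rose and the cyclin CYCB1-1 fell between 2 and 10 DAP, while 8.95% of MITE probes changed. The mean of the MITE probe ORSgTEMT00101141 was 0.12 ± 0.13 (SD, n = 3) at 2 DAP and 3.80 ± 0.23 at 10 DAP, a range of 3.68 (limma F-test, adjusted p = 6.39e-19). Of 19041 MITE probes 1704 changed with stage, and 937 of these (55.0%) had their highest mean at 10 DAP. Of 11819 gene and cDNA probes 6655 changed (56.3%), with 1981 highest at 2 DAP and 1657 (24.9%) highest at 10 DAP. Among Ty3-gypsy retrotransposons, long elements that move through an RNA copy, 98 of 751 probes changed and 84 of the 98 were highest at 10 DAP. Unclassified repeats went another way: of 302 changed probes 165 were highest at 3 DAP and 4 at 10 DAP. In all, 9769 probes changed.

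**Figure D1:**
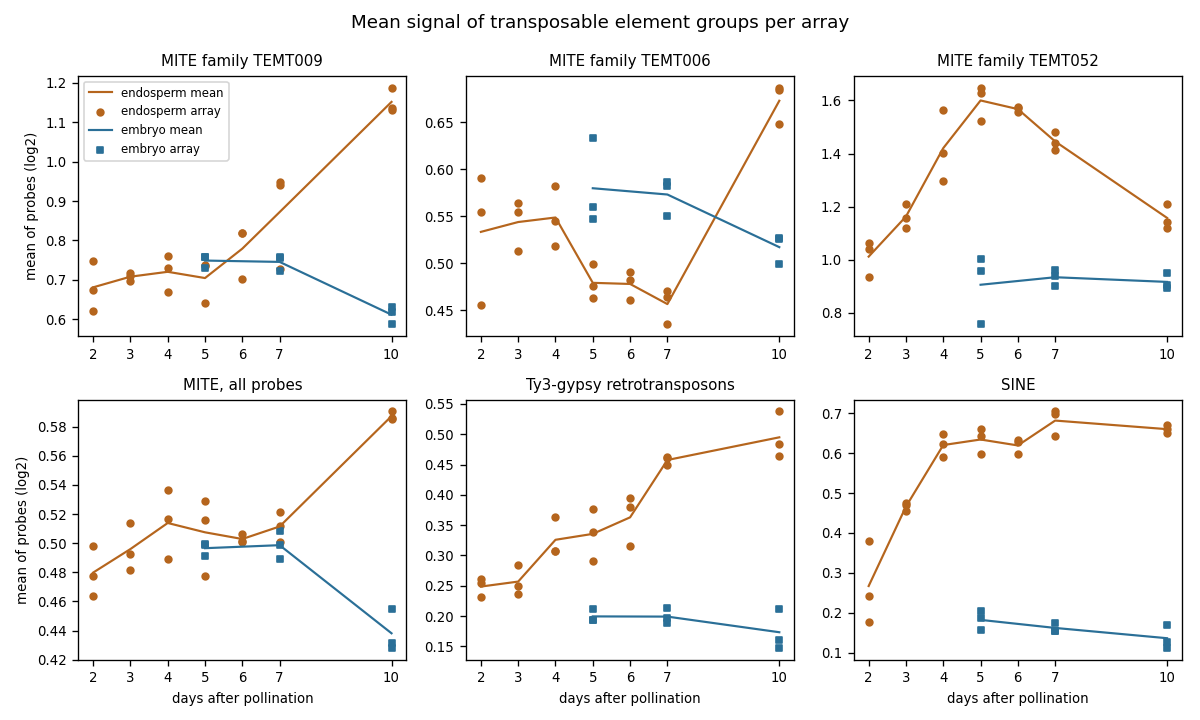
Mean log2 signal (vertical axis, scales differ) of 3 MITE families, all MITE probes, Ty3-gypsy and SINE retrotransposons against days after pollination; points are arrays, squares embryo arrays, and lines join group means. The TEMT009 mean was 0.87 at 7 DAP and 1.15 at 10 DAP in endosperm and 0.61 in embryo at 10 DAP, whereas TEMT052 peaked at 1.60 in endosperm at 5 DAP.

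From 2 to 3 DAP the starch synthesis genes on the array rose. SSIIa, a starch synthase, rose by 4.74 ± 0.63 (SE, adjusted p = 9.02e-06) to a mean of 10.34, and AGPS2, a subunit of the enzyme that makes the starch precursor ADP-glucose, rose by 3.82 ± 0.45 (adjusted p = 1.74e-06). AGO1c, an Argonaute of the small RNA pathway, rose by 1.71 ± 0.24 (adjusted p = 1.83e-05). Its list partner DCL3b, a Dicer, differed by -0.03, with means near background (0.37 at 2 DAP and 0.33 at 3 DAP). The largest rise of a transposable element was that of the SINE probe ORSiTERT00400039, a short retrotransposon, by 4.75 ± 0.61 (adjusted p = 5.84e-06), and the MITE probe ORSgTEMT01100006 rose by 2.60 ± 0.22 (adjusted p = 2.57e-08). CAB2R, a light-harvesting protein of green tissue, had a mean of 6.10 at 2 DAP and 5.12 at 3 DAP. The gene Os01g0606200, without a name in the files, had one of the largest falls and fell by 4.57 ± 0.29. In 28 cases a MITE probe was called higher and in 2 lower (24 and 1 adjusted over the list alone), and 22 of the 28 belonged to family TEMT009, which holds 18.1% of MITE probes. The MITE class did not pass the set test (camera adjusted p = 0.767). In all 745 probes rose and 618 fell, 1363 together, and the replicate block called 1370. The 2 DAP arrays were uneven, with an SD of 2.50 for SSIIa and 2.41 for the SINE probe, and in a fit of the 6 arrays alone the calls of the SINE probe (adjusted p = 0.071), SSIIa (adjusted p = 0.0777) and AGO1c (adjusted p = 0.0759) were lost.

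From 3 to 4 DAP the measured glutelin genes, GluA1 and GluA2, which encode storage proteins, rose. GluA1 rose by 8.60 ± 0.76 (adjusted p = 3.06e-08) from a mean of 0.24 ± 0.19 (SD, n = 3) to 8.84 ± 1.11, and GluA2 rose by 5.55 ± 0.39 (adjusted p = 9.04e-10). At 2 DAP 1 array had GluA1 at 4.32, and the GluA2 mean was 1.64. AGPS2 rose by a further 1.85 ± 0.45, and CYCB1-1, a cyclin of dividing cells, fell by 1.49 ± 0.30 (adjusted p = 0.00157). All 3 photosynthesis genes measured, markers of green maternal tissue, fell: RCA by 1.71 ± 0.33, CAB1R by 1.54 ± 0.16 and CAB2R by 1.31 ± 0.19. Centromere repeats rose as a class, with 69 probes higher and 0 lower of 2413 (camera adjusted p = 4.07e-11, and adjusted p = 0.0118 with an estimated correlation). Called MITE probes were 25 higher and 23 lower (24 and 22 adjusted over the list alone). Of the 25, 22 belonged to family TEMT052 (camera adjusted p = 3.89e-11, adjusted p = 0.937 with an estimated correlation). In all 637 probes rose and 507 fell. The extraction method changed between these stages, as did the marker genes of green tissue.

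From 4 to 5 DAP glutelin signal rose again and the cyclin fell further. GluA2 rose by 3.84 ± 0.39 (adjusted p = 6.58e-07), GluA1 by 2.64 ± 0.76 (adjusted p = 0.0352), and BiP1, a chaperone of the ER where storage proteins fold, by 1.36 ± 0.33 (adjusted p = 0.0113). CYCB1-1 fell by 2.27 ± 0.30 (adjusted p = 2.03e-05). Both starch synthesis genes stayed within 0.22 of their 4 DAP means and did not pass the test. The precursor of osa-MIR2091 rose by 2.08 ± 0.35 and that of osa-MIR2106 fell by 2.21 ± 0.24. Among MITE probes 8 rose and 24 fell (7 and 21 adjusted over the list alone), and 22 of the 24 belonged to TEMT009. In all 292 probes rose and 481 fell. The GluA1 call was lost without replicate 1 or 3 at 4 DAP (adjusted p = 0.206 and 0.0951) or replicate 1, 2 or 3 at 5 DAP (0.119, 0.0738 and 0.0763), without replicate 1 of every group (0.156) and with an intensity trend and robust variance (0.052). The BiP1 call was lost without replicate 3 at 4 DAP (adjusted p = 0.0819) or replicate 1 at 5 DAP (0.0806) and in a fit of the 6 arrays alone (0.0671).

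From 5 to 6 DAP the fewest probes changed of the 6 steps. Unclassified retrotransposons held the largest rises among elements: ORSiTERTOOT00138 rose by 2.92 ± 0.24 (adjusted p = 1.63e-07) and ORSiTERTOOT00217 by 2.83 ± 0.24 (adjusted p = 1.63e-07), the latter from a mean of 0.41 ± 0.17 (SD, n = 3). The MITE probe ORSgTEMT04900001 fell by 1.26 ± 0.28 (adjusted p = 0.00774), and the osa-MIR1855 precursor fell by 1.34 ± 0.20. None of the 13 list genes was called, and GluA2 differed by 0.64 ± 0.39. Of MITE probes 3 rose and 2 fell (1 and 2 adjusted over the list alone). In all 226 probes rose and 101 fell, 327 together, while without the fold minimum 1053 rose and 1400 fell. Without endosperm replicate 1 at 5 DAP 536 probes were called, array weights gave 666 (375 higher and 291 lower), leaving out replicate 1 of every group, added after seeing the data, gave 771 (394 and 377), and the replicate block gave 339.

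From 6 to 7 DAP the cyclin signal dropped to near background and several retrotransposons rose. CYCB1-1 fell by 2.11 ± 0.30 (adjusted p = 2.89e-05) to 0.52, and ORSiTERTOOT00217 rose by another 2.66 ± 0.24 (adjusted p = 4.01e-08) to 5.89. Ty3-gypsy retrotransposons had 18 probes higher and 0 lower (camera adjusted p = 0.000598, adjusted p = 0.991 with an estimated correlation). The MITE probes ORSgTEMT00900437 and ORSgTEMT00101141 rose by 1.60 ± 0.13 and 1.34 ± 0.10. A total of 16 MITE probes rose and 3 fell (16 and 2 adjusted over the list alone). In all 322 probes rose and 638 fell, and the replicate block called 975. In a fit of the 6 arrays alone the CYCB1-1 call was lost (adjusted p = 0.0533), and leaving out replicate 1 of every group called 1467 probes and ended the Ty3-gypsy call (adjusted p = 0.0519).

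From 7 to 10 DAP, the longest step and the one with the most changed probes, more MITE probes rose than fell. The MITE probe ORSgTEMT00901537 rose by 2.39 ± 0.15 (adjusted p = 1.76e-11) from 0.66 ± 0.16 (SD, n = 3) to 3.05 ± 0.29. Of 19041 MITE probes 340 were called higher and 120 lower (340 and 120 adjusted over the list alone), and the class moved up relative to other probes by a mean of 0.09 (camera adjusted p = 0.0158, adjusted p = 0.644 with an estimated correlation). Family TEMT009 held 192 of the 340 rises (camera adjusted p = 3.73e-11, adjusted p = 0.596 with an estimated correlation), and TEMT052 held 103 of the 120 falls (4.08e-08, adjusted p = 0.843 with an estimated correlation). The 340 probes had a median level of 1.24 at 2 DAP, 1.51 at 7 DAP and 2.81 at 10 DAP. With gene probes left out of the set test, a setting added after seeing the data, the class call was lost (0.0575, adjusted p = 0.0849).

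Other elements and genes moved at the same step. The retrotransposon probe ORSiTERTOOT00224 rose by 3.72 ± 0.15 (adjusted p = 2.44e-14), 170 probes of other DNA transposons rose and 15 fell, and 123 probes of unclassified repeats fell against 1 that rose. EMF2b, a subunit of the Polycomb PRC2 complex that represses genes through histone methylation, rose by 1.28 ± 0.10 (adjusted p = 1.28e-09). RAB16B, a dehydrin used as an embryo marker, fell by 1.49 ± 0.43 (adjusted p = 0.0114), and the photosynthesis gene CAB2R fell by 1.71 ± 0.19 (adjusted p = 2.09e-07). The osa-MIR1862c precursor rose by 3.08 ± 0.12 and the osa-MIR2091 precursor fell by 2.17 ± 0.35. In all 1535 probes rose and 1290 fell. The extraction method changed at this step.

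Between the ends of the endosperm series, at 10 against 2 DAP, storage and starch genes stood far higher and the cyclin and photosynthesis genes far lower. GluA2 rose by 10.04 ± 0.39 (adjusted p = 4.07e-16), GluA1 by 9.39 ± 0.76, AGPS2 by 6.26 ± 0.45, BiP1 by 2.08 ± 0.33 and EMF2b by 2.31 ± 0.10. CYCB1-1 fell by 5.81 ± 0.30 (adjusted p = 7.49e-14) and CAB2R by 4.22 ± 0.19, and CAB1R and RCA fell as well. The SINE probe ORSiTERT00400039 rose by 8.99 ± 0.61 (adjusted p = 1.02e-11) to 10.88 ± 0.09 (SD, n = 3), and the MITE probe ORSgTEMT01100006 rose by 6.37 ± 0.22 (adjusted p = 5.28e-17). The MITE probe ORSgTEMT04900001 fell by 5.29 ± 0.28 (adjusted p = 9.25e-14) and the osa-MIR2106 precursor by 6.85 ± 0.24 (adjusted p = 4.66e-17).

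As a class, 784 MITE probes were higher and 178 lower at 10 than at 2 DAP (784 and 172 adjusted over the list alone), with a mean shift of 0.17 relative to other probes (camera adjusted p = 0.023, adjusted p = 0.971 with an estimated correlation). Family TEMT009 held 564 of the 784. Ty3-gypsy retrotransposons had 84 probes higher and 7 lower (camera adjusted p = 0.00769, adjusted p = 0.971 with an estimated correlation). Of gene and cDNA probes 2012 were higher and 2890 lower; sorted values nearly coincide between arrays, so net falls of some probes are balanced by net rises of others. In all 3416 probes rose and 3308 fell. Extraction differed between these stages too, and the MITE class call was lost with gene probes left out of the set test (0.0497, adjusted p = 0.165).

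**Figure D2:**
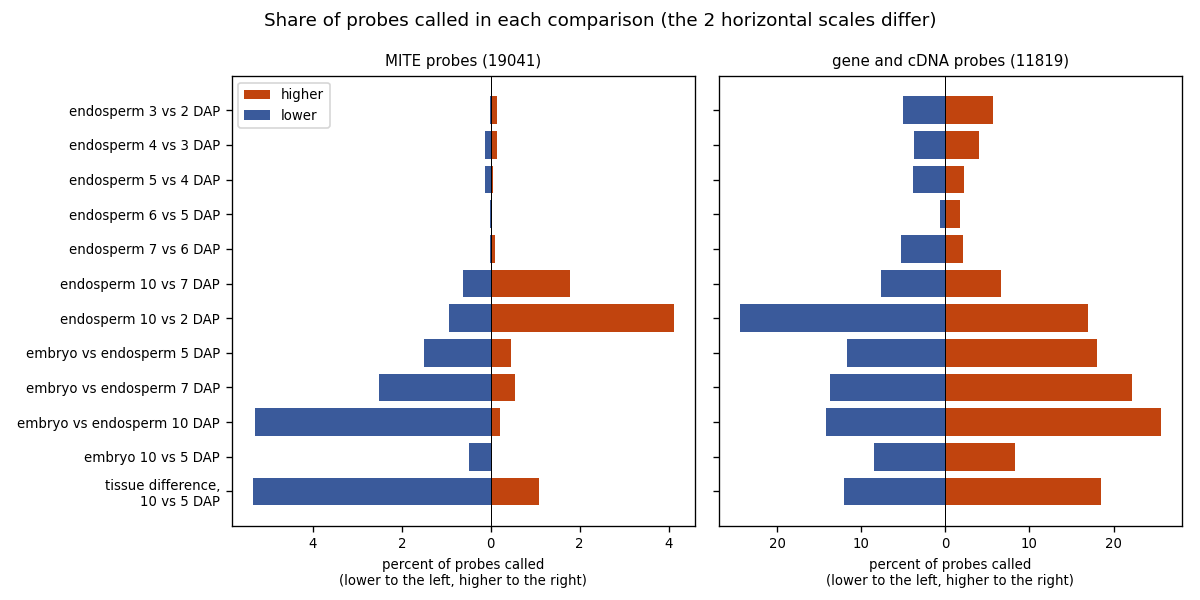
Percent of MITE probes (left) and of gene and cDNA probes (right) called in each comparison, lower as bars to the left of 0 and higher to the right, with a different scale in each panel. At 10 against 2 DAP 784 MITE probes were higher and 178 lower, and in embryo against endosperm at 10 DAP 40 were higher and 1010 lower.

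At 5 DAP embryo and endosperm already differed in the measured storage and starch genes and in the cyclin CYCB1-1. The former were lower in embryo, with differences of -8.13 ± 0.63 for SSIIa (adjusted p = 2.6e-10), -7.97 ± 0.39 for GluA2 (adjusted p = 7.91e-14) and -6.61 ± 0.45 for AGPS2, while CYCB1-1 was higher by 3.68 ± 0.30 (adjusted p = 6.76e-10) and AGO1c by 1.95 ± 0.24. The green maternal tissue marker CAB2R was lower in embryo too, with a difference of -3.52 (means of 0.36 and 3.88), while RCA and CAB1R were not called. The MITE probe ORSgTEMT02500037 was higher in embryo by 4.95 ± 0.26 (adjusted p = 2e-13), with a mean of 5.19 ± 0.98 (SD, n = 3) against 0.25 ± 0.04. Lower in embryo were ORSgTEMT01100006, with a difference of -4.62 ± 0.22, and the osa-MIR1877 precursor, with -5.50 ± 0.23. In embryo 88 MITE probes were higher and 284 lower (88 and 282 adjusted over the list alone), and the class did not pass the set test (camera adjusted p = 0.939), with a median difference of 0.02 and a mean of -0.01. Family TEMT052 held 181 of the 284 (camera adjusted p = 2.05e-13, adjusted p = 0.986 with an estimated correlation), and TEMT009 held 58 of the 88. In all 2320 probes were higher and 1951 lower. RAB16B was higher by 1.56 ± 0.43 (adjusted p = 0.00805), a call lost without embryo replicate 2 (0.70, adjusted p = 0.07) and in a fit of the 6 arrays alone (adjusted p = 0.246), and without replicate 1 the difference was 2.36.

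At 7 DAP the tissues differed in more probes. GluA2 and SSIIa were lower in embryo, with differences of -8.96 ± 0.39 (adjusted p = 5.58e-15) and -7.35 ± 0.63, while CYCB1-1 was higher by 5.54 ± 0.30 (adjusted p = 3.01e-13), AGO1c by 2.24 ± 0.24 and the osa-MIR408 precursor by 3.67 ± 0.27. CAB2R, a marker of green maternal tissue, was again lower in embryo, with means of 0.25 in embryo and 3.58 in endosperm, while RCA and CAB1R were not called. The SINE probe ORSiTERT00400039 was lower, with a difference of -8.79 ± 0.61, and Ty3-gypsy retrotransposons had 76 probes lower and 1 higher (camera adjusted p = 1.62e-05, adjusted p = 0.880 with an estimated correlation). At this stage 102 MITE probes were higher and 479 lower (102 and 477 adjusted over the list alone), and the class did not pass the set test (camera adjusted p = 0.602), with a median of 0.03 and a mean of -0.01. Of the 479, 239 belonged to TEMT009 and 149 to TEMT052. In all 2982 probes were higher and 2476 lower. BiP1 was lower, with a difference of -1.28 ± 0.33 (adjusted p = 0.0034), and its call was lost without endosperm replicate 1 (-0.89), without replicate 1 of every group (-0.97) and with array weights (-0.95).

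At 10 DAP more MITE probes differed between the tissues than at 5 or 7 DAP. In embryo 1010 MITE probes were lower and 40 higher (1010 and 40 adjusted over the list alone), a mean shift of -0.27 relative to other probes (camera adjusted p = 0.00134, adjusted p = 0.429 with an estimated correlation). Family TEMT009 held 670 of the 1010 (camera adjusted p = 3.23e-18, adjusted p = 0.429 with an estimated correlation), and its mean was 0.61 ± 0.02 (SD, n = 3) in embryo and 1.15 ± 0.03 in endosperm. The MITE probe ORSgTEMT01100006 had a difference of -6.73 ± 0.22 (adjusted p = 1.94e-17) and the SINE probe ORSiTERT00400039 one of -10.82 ± 0.61 (adjusted p = 3.59e-13). Ty3-gypsy retrotransposons had 93 probes lower and 1 higher (camera adjusted p = 0.00112, adjusted p = 0.782 with an estimated correlation). Some elements were higher in embryo, among them the MITE probes ORSgTEMT01900028 by 2.38 ± 0.14 and ORSgTEMT00501613 by 2.37 ± 0.09 and the retrotransposon ORSiTERTOOT00084 by 3.44 ± 0.07.

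Among genes at 10 DAP, RAB16B was higher in embryo by 8.92 ± 0.43 (adjusted p = 2.31e-14), CYCB1-1 by 4.36 ± 0.30 and RCA, the activase of the carbon-fixing enzyme, by 2.00 ± 0.33. Lower were GluA2, with a difference of -10.92 ± 0.39 (adjusted p = 9.69e-17), SSIIa, with -7.67 ± 0.63, and EMF2b, with -1.97 ± 0.10 (adjusted p = 6.61e-14). Unlike RCA, the green-tissue gene CAB2R was lower in embryo, with a difference of -1.69 (means of 0.18 and 1.87), and CAB1R was not called. Of gene and cDNA probes 3030 were higher and 1678 lower, a lean that the same balance ties to that of the repeats. In all 3357 probes were higher and 3268 lower. The MITE class call was lost with gene probes left out of the set test (-0.0884, adjusted p = 0.0556).

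**Figure D3:**
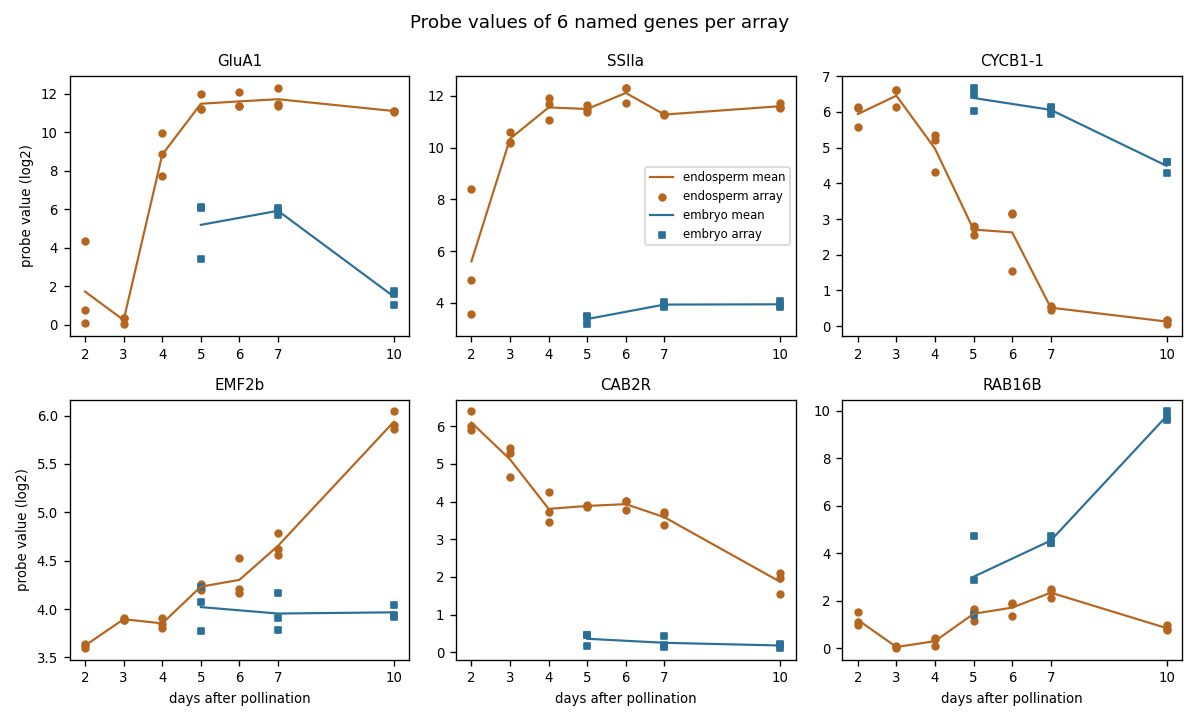
Log2 probe value (vertical axis) of 6 genes against days after pollination, with endosperm arrays as circles, embryo arrays as squares and lines through group means. GluA1 went from 0.24 at 3 DAP to 8.84 at 4 DAP in endosperm, CYCB1-1 fell to 0.13 at 10 DAP, and RAB16B reached 9.78 in embryo at 10 DAP.

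From 5 to 10 DAP the embryo gained dehydrin signal, while glutelin and cyclin signal fell. RAB16B rose by 6.76 ± 0.43 (adjusted p = 2.3e-11) to 9.78, and RCA rose by 2.30 ± 0.33 (adjusted p = 9.29e-06). GluA1 fell by 3.73 ± 0.76, GluA2 by 1.57 ± 0.39 and CYCB1-1 by 1.90 ± 0.30 (adjusted p = 4.04e-05). GluA1 stood at 5.19 ± 1.56 (SD, n = 3) in 5 DAP embryo against 11.48 in endosperm. A smaller trace of endosperm RNA in the 10 DAP embryo samples could also lower glutelin signal, which was not tested. The retrotransposon ORSiTERTOOT00061 rose by 3.74 ± 0.23 (adjusted p = 9.02e-12), and unclassified retrotransposons had 53 probes higher and 1 lower (camera adjusted p = 0.00131, adjusted p = 0.9999 with an estimated correlation). MITE probes went down more often, with 6 higher and 93 lower (6 and 92 adjusted over the list alone), 60 of the 93 in TEMT009, and ORSgTEMT02500037 fell by 2.90 ± 0.26. The MITE class did not pass the set test (camera adjusted p = 0.286), and did when gene probes were left out of it (-0.0720, adjusted p = 0.0444), a setting added after seeing the data. In all 1207 probes rose and 1158 fell.

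The change of the tissue difference from 5 to 10 DAP asks where that difference changed, whether it grew, shrank or reversed. The tissue difference of MITEs became more negative in 1019 probes and more positive in 206 (1018 and 205 adjusted over the list alone), a mean of -0.21 relative to other probes (camera adjusted p = 0.000957, adjusted p = 0.455 with an estimated correlation). Of the 1019, 764 belonged to TEMT009, and of the 206, 165 belonged to TEMT052. The MITE probe ORSgTEMT00101141 had a change of -3.44 ± 0.14 (adjusted p = 1.07e-14), and the osa-MIR2906a precursor one of -4.86 ± 0.56. Among genes, RAB16B had a change of 7.36 ± 0.61 (adjusted p = 1.86e-09) and EMF2b one of -1.76 ± 0.14 (adjusted p = 1.32e-09). In all 2743 probes had a positive and 3023 a negative change.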

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

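The tests of an array background shift, of a batch shared by replicate 1 arrays, of replicate 2 against 3 and of regroupings within replicate numbers were chosen only after the result was seen. Each difference named next changed between 5 and 10 DAP by a test of the change itself.

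The difference between embryo and endosperm changed in 5766 probes, where 2 of 100 regroupings of the arrays, the real one included, called as many; the highest other called 5899. The regroupings moved arrays freely between tissues and stages, which carries tissue and stage differences into the change. With 1 wrong grouping over the real count, they cannot decide on chance here. The MITE set moved by -0.206 (camera adjusted p = 0.000957, adjusted p = 0.455 with an estimated correlation), its forward probes by -0.151 (0.0248) and its reverse probes by -0.146 (0.0303), both with an adjusted p = 0.559 with an estimated correlation. The unclassified repeats set moved by 0.246 (adjusted p = 0.00285, adjusted p = 0.559 with an estimated correlation). The Ty3-gypsy set moved by -0.166 (adjusted p = 0.0472, adjusted p = 0.957 with an estimated correlation); its call was lost without endosperm replicate 1 (0.0939) or 2 (0.0507) at 5 DAP or 1 at 10 DAP (0.0736), or embryo replicate 1 at 5 DAP (0.102) or 10 DAP (0.0925). It was also lost with a replicate block (0.0552), renewed quantile normalization (0.0651), median centring (0.0652), array weights (0.15), the compared arrays alone (0.11), replicate 1 of every group left out (0.304) and gene probes left out (0.171).

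Among elements, the tissue difference of the MITE probe ORSgTEMT02500037 changed by -2.77 and shrank from 4.95 to 2.18. That of ORSgTEMT01100006 changed by -2.11 and grew from -4.62 to -6.73. The difference of the SINE probe ORSiTERT00400039 changed by -2.99. The MITE probe ORSgTEMT01900028 had a change of 1.21, the retrotransposon ORSiTERTOOT00084 one of 3.07 and the osa-MIR415 precursor one of 2.22. Among genes, the difference changed by -3.35 for GluA1, -2.95 for GluA2, -1.76 for EMF2b, 7.36 for RAB16B, 1.83 for CAB2R and 2.94 for RCA. The CAB2R difference shrank from -3.52 to -1.69, and that of RCA went from -0.93 to 2.00. The glutelin changes include the falls in embryo, where a trace of endosperm RNA was not told apart from embryo signal. The GluA1 call was lost without embryo replicate 2 (-2.92, adjusted p = 0.0651) or 3 (-2.89, 0.0658) at 5 DAP or 3 at 10 DAP (-3.12, 0.0536).

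MITE probes lower in embryo at 10 DAP were less so at 5 DAP. Endosperm RNA in the 5 DAP embryo samples is argued against: the 20 brightest endosperm genes called lower in embryo kept a median of 1.49% of their endosperm level there, with a range from 0.178 to 25.5%. Background in 5 DAP endosperm is argued against as the whole reason: 25.3% of the 1010 probes (256, exact 95% interval 22.7 to 28.1%) lay under 1 there. This count misses probes little over 1, which could hardly fall by 1. In 5 DAP embryo, however, 721 of the 1010 lay over 1 as well. The median of the 1010 probes was 1.53 at 5 DAP and 2.75 at 10 DAP in endosperm and 1.45 and 1.19 in embryo. A developmental divergence of the tissues may account for the change and stays open, beside the extraction of the 10 DAP endosperm.

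In endosperm 340 of 19041 MITE probes rose from 7 to 10 DAP and 120 fell. Genomic DNA in the labelling is argued against as the whole cause of this rise. Of 311 risers with a probe of the other orientation, 1.93% (6, exact 95% interval 0.711 to 4.15%) had that partner called too. The share was larger in the other comparisons with 10 DAP endosperm. It was 10.1% of 730 higher at 10 against 2 DAP and 11.1% of 936 lower in embryo at 10 DAP. For negative changes of the tissue difference it was 16.9% of 949. In the opposite directions 0 partners were called, but these lists were shorter, with 120, 178, 40 and 206 probes. Longer lists share more partners by chance, and that share was not computed. The contrast therefore cannot decide on a smaller part from genomic DNA, which stays open. A background shift cannot be judged from the 4761 dimmest MITE probes. They moved by a median of 0.018, from -0.125 to 0.139 between the 5th and 95th percentiles, but the normalization between arrays fixes that value. Such a shift would move probes of like level alike. The risers went from a median of 1.51 at 7 DAP to 2.81 at 10 DAP. Family TEMT052, with 103 of the 120 falls, went from a mean of 1.445 ± 0.034 (SD, n = 3) to 1.157 ± 0.048. The risers were picked by their rise, and their median stands beside the mean of a whole family. These values therefore cannot decide on a background shift either. The change of extraction as the whole cause cannot be told apart from stage. The 340 risers already moved up from 4 to 6 DAP, within one extraction method, by a median of 0.154 (235 of 340 up). The 10000 matched lists gave medians from -0.075 to 0.038. They were matched on level and not on family, and TEMT009 held 192 of the risers. Probes of one family may report a shared transcript, so this range may be too narrow. The early move may be a start of the rise but is small beside it.

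Replicate 1 arrays of endosperm deviated from their groups together: in 15 of 21 pairs of stages the deviations correlated over 0.1, across probes that are not independent. Replicates 2 and 3 did so in 14 and 13 pairs, which centring on a group mean that holds replicate 1 can give: the difference of replicates 2 and 3, free of replicate 1, correlated over 0.1 in 0 of 21 pairs (from -0.132 to 0.094). A processing batch shared by these arrays may account for this. A harvest time shifted the same way at all stages is argued against. The deviation was correlated with the change from the stage before to the stage after, and the correlation ran from -0.306 to 0.218 over 5 stages. At 5 and 6 DAP, within one extraction method, the correlation was 0.002 and 0.044. At 3, 4 and 7 DAP the change between neighbouring stages spans a change of extraction as well. There the correlation was 0.218, -0.306 and -0.062, and development cannot be told apart from extraction. Harvest differences that vary between stages stay open. Replicate 1 had the lowest array weight in each endosperm stage, 0.19 to 0.51 from 2 to 7 DAP, but the labels give no batch.

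Regrouping the 21 endosperm arrays gave at most 7130 changed probes against the real 9769. Only 1 of 100 regroupings, the real one, reached that count, which argues against chance there. So few regroupings cannot resolve a share under 1 of 100. In 12 of 21 pairs of endosperm stages the deviations of all 3 replicate numbers correlated over 0.1. A shared deviation of replicate 1 alone can give this. Regrouping within the numbers gave at most 8561, again under the real count in all but the real 1 of 100. The replicate block called 9853. For comparisons of 3 with 3 arrays the 10 splits are too few for a share under 0.05. The real count and the highest other were 1363 and 19 for 3 against 2 DAP, 1144 and 2 for 4 against 3, 773 and 100 for 5 against 4, 327 and 25 for 6 against 5, 960 and 140 for 7 against 6, 2825 and 28 for 10 against 7, 6724 and 0 for 10 against 2, 4271 and 71 for the tissues at 5 DAP, 5458 and 0 at 7 DAP, 6625 and 0 at 10 DAP, and 2365 and 0 for embryo at 10 against 5 DAP. In each the real split alone, 1 of 10, reached its count.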

How the results depend on the processing

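Leaving out replicate 1 of every group and leaving gene probes out of the set test were chosen after seeing the data. Renormalization, median centring, the filter on dim probes, the variance model and fits of the compared arrays alone kept all 13 counts within 1.5 times. Renormalization and centring could move little, since sorted values already nearly coincided between arrays. The filter removed probes near background, so it is a weak check as well. Of named probes under all alternatives 7759 values stayed called or not called as before, 24 gained and 149 lost a call; of class sets 2739 stayed so, 56 gained and 91 lost one; no called direction reversed. Dim probes limit the reach, since signal under 1 is near background.

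Without the fold minimum the counts were 21660 for the stage F-test, 4445 for 3 against 2 DAP, 4487 for 4 against 3, 2917 for 5 against 4, 2453 for 6 against 5, 3872 for 7 against 6, 12105 for 10 against 7, 16710 for 10 against 2, 11789, 16596 and 16195 for the tissues at 5, 7 and 10 DAP, 7129 for embryo 10 against 5 and 11852 for the change of the tissue difference, since more probes then pass. For 6 against 5 DAP array weights gave 666, and leaving out replicate 1 gave 771 there and 1467 for 7 against 6; the cause was not tested. The share of rises at 6 against 5 DAP, 69.1%, was 42.9% without the fold minimum, 56.3% with weights and 51.1% without replicate 1. Shares near even crossed 50% under these settings: 50.8% at 10 against 2 DAP (lowest 49.3%), 50.7% in the tissues at 10 DAP (45.3%) and 51.0% for embryo 10 against 5 (45.3%).

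With an estimated correlation 1 of 87 set calls held, and the MITE set lost its call at 10 against 7 DAP (0.0920, adjusted p = 0.644), 10 against 2 (0.171, 0.971), in the tissues at 10 DAP (-0.271, 0.429) and in the change of their difference (-0.206, 0.455). Against other repeats only, it was 0.0575 (adjusted p = 0.0849) at 10 against 7, 0.0497 (0.165) at 10 against 2 and -0.0884 (0.0556) in the tissues at 10 DAP, all no longer past the threshold, and -0.0720 (0.0444), newly past it, for embryo 10 against 5; the cause was not tested.

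Leaving out 1 array at a time gave 9561 to 10123 for the F-test, 1240 to 1535 for 3 against 2, 958 to 1351 for 4 against 3, 617 to 984 for 5 against 4, 233 to 536 for 6 against 5, 848 to 1255 for 7 against 6, 2652 to 3005 for 10 against 7, 6583 to 6803 for 10 against 2, 4147 to 4515, 5287 to 5755 and 6508 to 6728 for the tissues, 2320 to 2502 for embryo and 5616 to 5995 for the change of the tissue difference.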

Other observations

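Some of the 864 microRNA precursor probes differed between the tissues: 18 were higher and 22 lower in embryo at 5 DAP, 11 and 29 at 7 DAP and 16 and 29 at 10 DAP. The class did not pass the set test (camera adjusted p = 0.234, 0.361 and 0.974). The osa-MIR166a precursor was higher in embryo by 2.18 ± 0.16 at 5 DAP, 1.74 ± 0.16 at 7 DAP and 2.38 ± 0.16 at 10 DAP (SE, n = 3 per group), each called by limma. Lower in embryo at 10 DAP were the precursors of osa-MIR2091, with a difference of -4.01 ± 0.35, and osa-MIR1877, with -4.55 ± 0.23. The probes match precursor sequences in either orientation (410 forward and 454 reverse), and the orientation of each named probe is not given here. Mature microRNAs were not measured.

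Many probes that differed between the tissues recurred across stages. Of MITE probes 79 were lower in embryo at all of 5, 7 and 10 DAP, where 5.65 would be shared if the stages were independent among the 4933 MITE probes over 1 in at least 1 group. Higher in embryo at all 3 were 7 MITE probes (0.0148). Of gene and cDNA probes over 1, 1459 were higher (201) and 728 lower (44.8) at all 3, so recurrence was not particular to elements. For 22 Ty3-gypsy (15.6 expected among 116 probes over 1) and 10 SINE probes (5.33 among 15) lower at all 3 the excess was smaller, and none of these was tested. The 784 MITE probes higher in endosperm at 10 than at 2 DAP and the 479 lower in embryo at 7 DAP rest on separate arrays and shared 220 probes, where independence among the 4933 gives 76.1. Probes of one family are not independent, which these expected numbers leave out of account. The level of ORSgTEMT01100006 in embryo stayed between 0.06 and 0.10, near background, at all 3 stages.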
